A study of Mus musculus with 125 samples.

How the data were processed

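Bulk RNA sequencing of polyadenylated RNA was done on brain tissue of Gpr34 knockout (KO) and wild-type (WT) C57BL/6J mice aged 18 days or 3 months. Per the labels the mice were male, each brain region of each animal gave its own library from a stranded mRNA kit, and libraries were read as paired ends on a NovaSeq X. The region labels are Hipp, MC, SSC, Hind and Thal, which the labels do not expand, so they are used as written. The labels put 124 of 125 libraries in 20 groups by region, age and genotype, with 1 library per mouse and region, and the mouse was taken as the replicate. The remaining library has no region, age, genotype or mouse in its labels and entered no comparison.

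The deposited files give, per library, the expected counts of each transcript as estimated by Salmon per the submitters' processing notes, with no scaling for depth or length. They also give deposited TPM values, which per the file headers are scaled for effective length and which add up to the same total in each library. A further deposited column holds another unit, the effective transcript length in bases, which served only for length offsets. The submitters' processing notes name Salmon, DESeq2 and the build mm10, with no version, setting or role. The labels speak of downsampling, but the totals of expected counts ranged from 14.56 M to 578.18 M per library with a median of 36.98 M, and 5 libraries exceeded 100 M.

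Transcripts were joined by Ensembl ID to the GENCODE M21 annotation of GRCm38, the assembly that mm10 stands for. Of 93717 transcripts 92962 matched, and the 755 unmatched ones held 0.172% to 0.252% of the counts of a library. Whether the authors quantified against that release is not stated. Expected counts were summed over the transcripts of each of 28241 genes and rounded to whole numbers. Levels are given as CPM, the count over the library's deposited total in M counts (M for mega), with the standard deviation (SD) over mice, and an offset of 0.5 was added to CPM before log2 where marker scores are given. A library without counts of a gene can hold it at up to the level of 3 counts. That floor covers counting error alone, since the reads carried no molecular identifiers. The smallest total, 14.56 M counts, sets the coarsest resolution.

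KO and WT libraries were compared within each region and age by the edgeR 4.0.16 quasi-likelihood test with robust dispersion and TMM factors, after edgeR's filter on low counts by genotype. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the genes tested, and all tests were 2-sided. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F. To combine regions, counts were summed per mouse, over all 5 regions at 18 days and over Hipp, SSC, Hind and Thal at 3 months and across ages, since 1 WT mouse had no library labelled MC. The difference of the KO effect between ages was tested as an interaction on these sums, its difference between regions as an edgeR F test of the genotype by region terms with the mouse as a block, and the effect of age within WT mice per region and on sums. R 4.3.3 was used.

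Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 33 lists of brain cell types, microglial states, clearance of dying cells and stress or signalling programmes. Gpr34 itself was left out of its lists. Each call was repeated with a correlation estimated from the data. Medians of lists are of edgeR log2 fold changes, except that those under an alternative, in other splits and for the difference between ages are of voom log2 fold changes. For each comparison the 6 lists with the smallest p are described with up to 4 members each, and members past the threshold are counted over all genes and adjusted over the list alone. Some single genes are not reported here.

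The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. That rule takes Gpr34 and its chromosomal neighbours, and among genes past the threshold with a mean of 1 CPM or more, predicted genes excluded, the largest changes, which are 12 up and 12 down for sums, 4 up and 4 down for a region and 3 up and 3 down for age within a region. Where fewer than 5 genes passed for sums, or fewer than 2 for a region, it takes the 5 or 2 genes of any kind or level with the smallest p, and for interactions the 2 with the smallest p where none passed. Marker scores are the mean log2 CPM of 7 lists of region markers.

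Alternatives fixed beforehand were RLE factors, no filter on low counts, DESeq2 1.42.0, offsets for average transcript length, the leading number of the mouse ID (the ID prefix, which the labels do not explain while naming a single batch) as a covariate, where prefixes with both genotypes hold 4 KO and 5 WT mice at 18 days and 5 KO and 3 WT mice at 3 months, 1 surrogate variable from sva 3.50.0 as a covariate, all libraries of an age in a joint fit, voom with the mouse as a replicate block, sums without Hipp or MC, no replicate block, and each mouse left out in turn. Alternatives chosen after the data were seen left out libraries whose Gpr34 level was at odds with their labels, left out libraries whose marker scores lay nearer another region label, thinned every library to 14 M counts, took each library's slope of log2 CPM on GC share (genes of 5 CPM or more) as a covariate, and used the ID prefix with the gene lists, alone and without the doubtful libraries. The libraries left out for Gpr34 include the SSC library of mouse 81_1, whose own Gpr34 level lies within the WT range. The number of lists described, the test of lists between ages and a score of age for SSC libraries were also chosen after the data were seen.

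Each result across many genes was set against 100 splits of the same mice drawn with a fixed seed, the real one included, in groups of the same sizes. Splits of the tests between regions kept the dispersion trend of the real fit. The tests were tried on simulated counts with 200 changed genes per comparison and the sizes of the real groups. At a 2-fold change edgeR recovered 91% of changed genes for sums at 18 days and 88.1% at 3 months, with 8 false calls among 181 and 8 among 169. DESeq2 made 47 false calls among 233 and 50 among 232. The choice of edgeR for the tests predates this simulation. Of 6 lists changed 1.5-fold in simulated counts camera recovered 6 at each age, and it also called 2 unchanged lists at 18 days and 0 at 3 months. Those counts were drawn for each gene by itself, without correlation between genes. In the real KO comparisons the estimated correlation of a list reached 0.937, so the simulation does not test the preset of 0.01. A 1.5-fold change is also larger than the median of most lists called between KO and WT. Libraries were checked for near-identical pairs, and none was found among 7750 pairs, the lowest chi-square per gene being 7.24. Libraries of different regions from the same mouse deviated from their group means more alike than those of other mice of that age and genotype, with a median correlation across genes, which are not independent replicates, of 0.228 against -0.0653 at 18 days and 0.108 against -0.0117 at 3 months. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.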

Results

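The series holds RNA sequencing of brain regions from mice that lack Gpr34, a G protein-coupled receptor for lysophosphatidylserine that microglia express, and from wild-type mice. Its title concerns the removal of dying brain cells by microglia. At 18 days there were 12 mice, 7 labelled KO and 5 labelled WT, each with a library from Hipp, MC, SSC, Hind and Thal. At 3 months there were 13 mice, 8 labelled KO and 5 labelled WT, again with 5 regions each, except that MC had 4 WT libraries. Library totals ranged from 14.56 to 578.18 M expected counts, with group medians between 17.3 M in Hipp KO libraries at 3 months and 61.27 M in SSC KO libraries at 18 days.

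Gpr34 (ENSMUSG00000040229.11, GRCm38 chromosome X, 13632089 to 13640858) shows whether the genotype labels hold. In the KO groups at 3 months its mean lay between 0.0419 CPM ± 0.0397 (SD, n = 8) in Hipp and 0.0703 CPM ± 0.0477 (SD, n = 8) in SSC. In WT mice of that age the mean was 8.999 CPM ± 3.93 (SD, n = 4) in MC and 6.62 ± 3.75 (SD, n = 5) in Thal. It was 5.02 ± 3.15 (SD, n = 5) in SSC, 4.74 ± 3.87 (SD, n = 5) in Hind and 2.77 ± 2.40 (SD, n = 5) in Hipp. At 18 days WT means ranged from 3.12 CPM ± 2.98 (SD, n = 5) in MC to 7.16 ± 4.39 (SD, n = 5) in SSC. KO means of that age ranged from 0.231 ± 0.472 (SD, n = 7) in MC to 1.23 ± 2.87 (SD, n = 7) in Thal.

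The level went against the label in 3 mice. The 5 libraries labelled KO mouse 89_11 held Gpr34 at 1.30 CPM in MC, 3.58 in SSC, 6.43 in Hind, 6.76 in Hipp and 7.74 in Thal. The other 30 KO libraries of that age held at most 0.227 CPM. The libraries labelled WT mouse 81_1 held 0 CPM in Hind and Hipp and 0.05 CPM in Thal, but 8.07 CPM in SSC. The SSC library labelled WT mouse 88_1 held 0.022 CPM. Without these, WT libraries ranged from 1.19 to 11.6 CPM at 18 days and from 0.866 to 11.9 CPM at 3 months. KO libraries at 3 months then reached at most 0.177 CPM. Over all libraries the log2 ratio of the KO mean to the WT mean was -3.79, and it was -6.35 without the libraries in doubt. Since those libraries, apart from the SSC library of mouse 81_1, were picked by their Gpr34 level, the second value is not independent of that choice. Every comparison below keeps the labels as given unless it says otherwise.

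**Figure D1:**
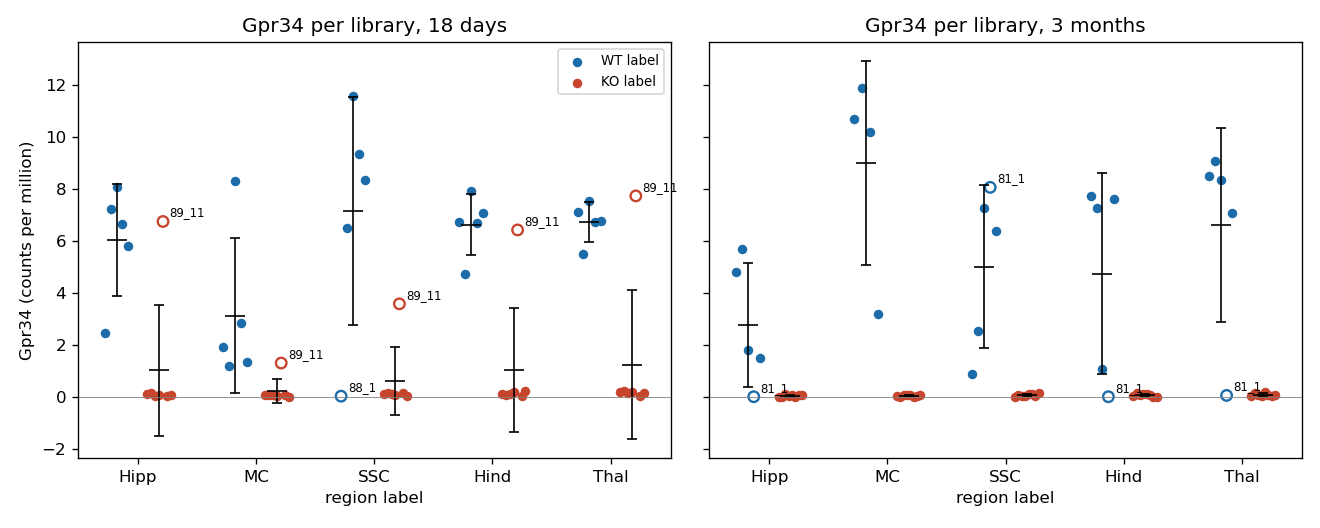
Gpr34 in CPM (count over library total in M counts) in each library (points), by region label, age and genotype label, with the group mean and SD in black. Open circles mark the libraries of mice 89_11 and 81_1 and the SSC library of mouse 88_1. The other KO libraries lie at or below 0.227 CPM and the other WT libraries at or above 0.866 CPM.

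Xist, the non-coding RNA of X inactivation in females, and the Y-linked gene Ddx3y gave a further view of the labels, which call the mice male. Xist lay between 191 and 499 CPM in the 5 libraries of mouse 89_11 and between 286 and 609 CPM in those of WT mouse 88_8, with Ddx3y at or below 0.304 CPM and 0.482 CPM. In the other mice Xist reached at most 2.90 CPM and Ddx3y was at least 19.2 CPM.

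At 18 days edgeR called no gene between mice labelled KO and mice labelled WT in sums over regions, Gpr34 included. In these sums Gpr34 was lower in mice labelled KO with a log2 fold change of -2.78 ± 1.12 (SE, n = 7 and 5), yet its edgeR adjusted p was 0.963. Without mice 89_11 and 88_1 it was the gene called, at -5.98. The 5 genes with the smallest p did not pass either, with an adjusted p of 0.963 each. They were Pnpla3, a lipase gene of lipid droplets, at -0.48 ± 0.10 (SE) and Pik3cd, a catalytic PI3-kinase subunit gene, at -0.27 ± 0.06 (SE). The others were the X-linked gene Xlr4b at -2.66 ± 0.55 (SE), Gm2861 at -2.39 ± 0.53 (SE), and complement factor B (Cfb) at 1.31 ± 0.28 (SE). Each of these 5 lay beyond the WT median in 7 of 7 KO mice. edgeR called 0 genes, with 460 at an unadjusted p under 0.05. DESeq2 called 4, Pnpla3, Xlr4b, Cfb and CR974586.1. On the separate libraries of all 5 regions, limma voom with the mouse as a block called Gpr34 alone.

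Among gene groups at 18 days, camera called 11 of the 33 lists. Interferon response genes were higher in KO mice, with 27 of 28 members above and a median log2 fold change of 0.25 (adjusted p = 9.44e-06, and adjusted p = 0.75 with an estimated correlation). The list was not called with the ID prefix as a covariate, at 0.05 (adjusted p = 0.544) against 0.19 by voom without it. Its members Ifit1 at 1.10 ± 0.40 (SE), Ifit3 at 0.74 ± 0.28 (SE), Usp18 at 0.79 ± 0.36 (SE) and Ifi27l2a at 0.43 ± 0.18 (SE) did not pass by themselves. KO mouse 89_6 stood apart for Ifit3 (10.22 CPM, the next being 5.944) and Usp18 (2.078 CPM, the next being 0.9459). Antigen presentation had 14 of 16 members above (median 0.16, adjusted p = 0.00105, and adjusted p = 0.75 with an estimated correlation). It was not called with the prefix, at 0.03 (adjusted p = 0.544) against 0.14. Among its members H2-T23 lay at 0.60 ± 0.32 (SE), Cd74 at 0.36 ± 0.20, H2-Eb1 at 0.35 ± 0.20 and Tap2 at 0.19 ± 0.11. Complement had 16 of 18 above (median 0.15, adjusted p = 0.00322, and adjusted p = 0.75 with an estimated correlation). This list too was not called with the prefix, at 0.05 (adjusted p = 0.989) against 0.11. Besides Cfb, C4b lay at 0.38 ± 0.13 (SE), C2 at 0.18 ± 0.10 and Cd59a at 0.57 ± 0.34.

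Proliferation genes were lower, with 19 of 21 members below and a median of -0.24 (adjusted p = 7.63e-05, and adjusted p = 0.75 with an estimated correlation). They were called as higher with the ID prefix as a covariate, at 0.18 (adjusted p = 6.79e-08) against -0.33 by voom without it. Mcm2 lay at -0.23 ± 0.18 (SE), Bub1 at -0.50 ± 0.40, Cenpf at -0.39 ± 0.33 and Top2a at -0.44 ± 0.40. Immature neuron genes had 19 of 20 members below (median -0.20, adjusted p = 9.37e-05, and adjusted p = 0.75 with an estimated correlation). They too were called as higher with the prefix, at 0.13 (adjusted p = 0.021) against -0.30. Neurod1 lay at -0.64 ± 0.28 (SE), Draxin at -0.78 ± 0.42 and Nrep at -0.38 ± 0.32, against Dlx6os1 at 0.46 ± 0.28. Homeostatic microglia genes, markers of resting microglia, had 18 of 24 members below (median -0.08, adjusted p = 9.37e-05, and adjusted p = 0.75 with an estimated correlation). With the prefix they were at -0.11 (adjusted p = 0.000353) against -0.10. An absolute median as large came up in 12 of 100 splits of these mice, the real one included. P2ry12 lay at -0.40 ± 0.16 (SE), P2ry13 at -0.30 ± 0.14, Hpgds at -0.20 ± 0.10 and Slc2a5 at -0.20 ± 0.11. Within these 6 lists 0 members passed by edgeR over all genes, and adjusted over the list alone 1 did, Cfb in complement. The 3 mice with ID prefix 89 are all labelled KO, and their SSC libraries had an age score (defined in the figure on SSC libraries) between -0.003 and 0.098, against -0.505 to -0.34 for those with prefix 88 other than 88_1 and a median of 0.589 at 3 months. Of the 6 lists, interferon response, antigen presentation and complement were also higher, and proliferation and immature neurons lower, at 3 months than at 18 days in WT mice. Cerebellum marker scores in Hind at 18 days reached 7.47 in WT and 4.96 in KO libraries.

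The other 5 calls at 18 days were oligodendrocyte precursors (median -0.07, adjusted p = 0.00803) and mitochondrially encoded genes (-0.09, 0.0314), which were lower. Also called were heat shock (0.16, 0.0137), inhibitory neurons (0.27, 0.0142) and astrocytes (0.08, 0.0263), which were higher. Their adjusted p was 0.75 with an estimated correlation, or 0.821 for the mitochondrial list. Of these 5 lists 0 were called with the ID prefix as a covariate. Oligodendrocyte precursors turned to 0.07 (adjusted p = 0.111), heat shock to -0.04 (0.135) and astrocytes to -0.01 (0.961), with mitochondrial genes at -0.06 (0.243) and inhibitory neurons at 0.07 (0.754). Astrocytes were also not called with equal totals (adjusted p = 0.266) or with the GC slope as a covariate (0.0969), nor mitochondrial genes with that slope (0.0991). Without the mice in doubt 7 lists were called. Complement (0.08, adjusted p = 0.0639), mitochondrial genes (-0.09, 0.0639), inhibitory neurons (0.14, 0.103) and oligodendrocyte precursors (-0.05, 0.188) were not among them.

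By region at 18 days, edgeR called 1 gene in Thal and 0 in Hipp, MC, SSC and Hind. Adgrd1, an adhesion G protein-coupled receptor, was higher in Thal, with 5.24 CPM ± 1.38 (SD, n = 7) against 1.25 ± 0.14 (SD, n = 5). Its log2 fold change was 2.15 ± 0.23 (SE), shared by 7 of 7 KO libraries (edgeR adjusted p = 0.0085). Pdyn, the precursor of dynorphin, came next at 1.54 ± 0.23 (SE, adjusted p = 0.155). Without WT mouse 88_1, 88_8, 88_9 or 88_11 edgeR called 0 genes in Thal, and without KO mouse 89_11 or 89_12 it called 2. Adgrd1 was also not called with 1 surrogate variable as a covariate, in the joint fit of all libraries, or without libraries nearer the markers of another region. Those were 3 of 7 KO and 0 of 5 WT libraries of Thal, that of mouse 89_11 among them, and without them Gpr34 was the gene called.

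The genes with the smallest p by edgeR in the other regions did not pass by that test. In Hipp these were Car13 at 4.16 ± 0.95 (SE) and the cadherin gene Cdh1 at 3.37 ± 0.79, each above the WT median in 7 of 7 KO libraries (adjusted p = 0.929). In MC they were Ugt1a6a at 1.63 ± 0.29 (SE) and Pcdhgb1 at 0.53 ± 0.12 (adjusted p = 0.934). In SSC they were DXBay18 at 4.72 ± 0.68 (SE, adjusted p = 0.101) and the repressor gene Bcor, a neighbour of Gpr34, at 0.47 ± 0.10 (adjusted p = 0.999). In Hind they were Pnpla3 at -1.01 ± 0.18 (SE) and the tight junction gene Cldn3 at -2.80 ± 0.52 (adjusted p = 0.74). Gpr34 had log2 fold changes from -3.74 ± 0.90 (SE) in MC to -2.35 ± 1.07 in Thal, with adjusted p from 0.446 to 0.999. Without the libraries in doubt it was called in all 5 regions. At an unadjusted p under 0.05 edgeR had 381 genes in Hipp, 469 in MC, 487 in SSC, 899 in Hind and 1786 in Thal. DESeq2 called 6, 5, 3, 48 and 101. With a mouse left out edgeR called 1 gene in Hipp (89_11), MC (88_1 or 89_11), SSC (88_7) and Hind (88_1, 88_6 or 89_11).

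At 3 months the sums of KO mice differed from those of WT mice in Gpr34, at 0.0669 CPM ± 0.0439 (SD, n = 8) against 5.64 ± 1.64 (SD, n = 5). Its log2 fold change was -6.31 ± 0.39 (SE), lower in 8 of 8 KO mice (edgeR adjusted p = 6.11e-06). The next genes did not pass but shared their direction in 8 of 8 KO mice. The small heat shock protein gene Hspb1 was at 17.4 CPM ± 3.08 (SD, n = 8) against 10.3 ± 1.45 (SD, n = 5), a log2 fold change of 0.76 ± 0.12 (SE, edgeR adjusted p = 0.195). The microglial ADP receptor gene P2ry12 was at 15.7 CPM ± 1.49 (SD, n = 8) against 22.5 ± 2.22 (SD, n = 5), or -0.51 ± 0.09 (SE, edgeR adjusted p = 0.294). The microglial fractalkine receptor gene Cx3cr1 stood at -0.38 ± 0.08 (SE) and Ahsa2, which encodes an HSP90 co-chaperone, at 0.30 ± 0.06 (SE), both with an adjusted p of 0.794. edgeR called 1 gene, with 1058 at an unadjusted p under 0.05, and without KO mouse 7_3 it called 2. DESeq2 called 19 in the sums. On the separate libraries of all 5 regions, MC included, limma voom with the mouse as a block called 41, of which 10 were shared. The shared ones, whose names were looked up after the counts were seen, are Gpr34, P2ry12, P2ry13, Cx3cr1, Siglech, I830077J02Rik, Hspb1, Hspa1b, Hspa5 and Ahsa2.

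Heat shock genes, the chaperones of the protein folding response, were higher in KO mice at 3 months in 14 of 14 members, with a median log2 fold change of 0.19 (camera adjusted p = 2.99e-14, and adjusted p = 0.00735 with an estimated correlation). Over all genes 0 members passed by edgeR, and 10 of 14 did adjusted over the list alone. Among these was Hspb1, as above, and Hspa5, the chaperone BiP of the endoplasmic reticulum, at 0.44 ± 0.10 (SE). Others were the inducible Hsp70 gene Hspa1b at 0.79 ± 0.18 (SE) and the co-chaperone gene Dnajb1 at 0.31 ± 0.08 (SE). Over all genes none of these 4 passed (adjusted p = 0.195 for Hspb1 and 0.794 for the rest). The median was 0.13 with the ID prefix as a covariate (adjusted p = 8.36e-09) and 0.17 without mouse 81_1 (adjusted p = 4.88e-15).

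Homeostatic microglia genes were lower in 20 of 24 members, with a median of -0.20 (camera adjusted p = 7.68e-14, but adjusted p = 0.344 with an estimated correlation). Over all genes 0 passed by edgeR, and adjusted over the list alone 12 of 24 did, all lower. These included P2ry12 and Cx3cr1, the microglial lectin gene Siglech at -0.36 ± 0.08 (SE), the receptor gene P2ry13 at -0.39 ± 0.09 and the myeloid transcription factor gene Spi1 at -0.37 ± 0.09. Other microglial genes of the list lay near 0, such as Tyrobp at -0.03 ± 0.06 (SE), Fcer1g at 0.00 ± 0.07 and Ctss at 0.09 ± 0.05. The median was -0.25 with the ID prefix as a covariate and -0.23 without mouse 81_1.

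**Figure D2:**
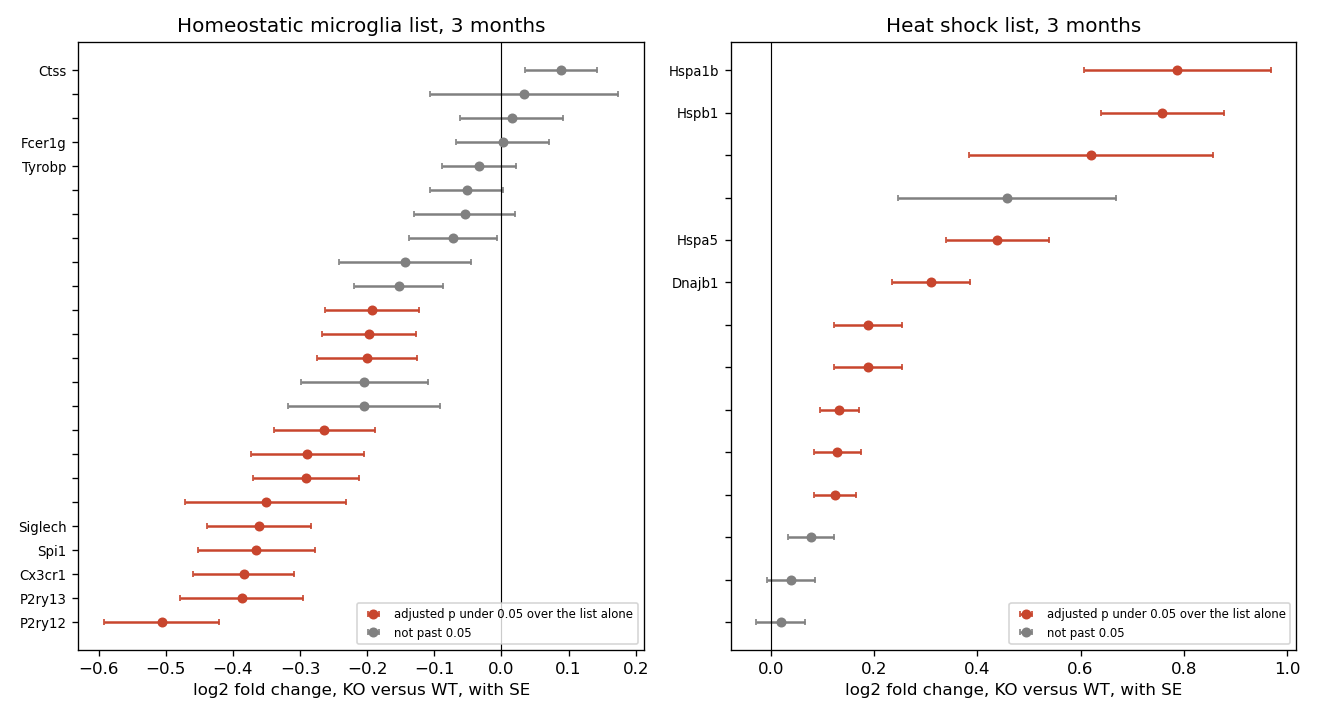
Log2 fold change of KO versus WT mice at 3 months, in counts summed over Hipp, SSC, Hind and Thal, with its SE, for each member of the homeostatic microglia list (left) and the heat shock list (right), with the names of the members given above for these lists. Red points have an edgeR p adjusted over the list alone under 0.05, which were 12 of 24 members on the left and 10 of 14 on the right.

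The other lists described at 3 months lost their call with an estimated correlation. Myelin genes of mature oligodendrocytes were higher in 19 of 20 members, with a median of 0.28 (adjusted p = 2.78e-06, and adjusted p = 0.411 with an estimated correlation). Anln lay at 0.53 ± 0.19 (SE), Ermn at 0.45 ± 0.19, Trf at 0.41 ± 0.19 and Apod at 0.35 ± 0.16. With the ID prefix as a covariate the list was not called (0.14 against 0.27 by voom without it, adjusted p = 0.0778). Mitochondrially encoded genes were higher in 13 of 13 members (median 0.13, adjusted p = 2.78e-06, and adjusted p = 0.405 with an estimated correlation). Among them mt-Nd4l lay at 0.26 ± 0.10 (SE), mt-Nd2 at 0.24 ± 0.12, mt-Nd4 at 0.16 ± 0.09 and mt-Cytb at 0.12 ± 0.06. Erythroid genes, which come with blood in the tissue, were lower in 8 of 10 members (median -0.63, adjusted p = 2.64e-05, and adjusted p = 0.355 with an estimated correlation). Slc4a1 lay at -0.95 ± 0.25 (SE), Alas2 at -0.77 ± 0.32 and Hbb-bt at -0.62 ± 0.32. Synapse genes were lower in 28 of 30 members (median -0.14, adjusted p = 2.64e-05, and adjusted p = 0.411 with an estimated correlation). Grin1 lay at -0.16 ± 0.07 (SE), Syp at -0.13 ± 0.06, Camk2b at -0.23 ± 0.11 and Dlg4 at -0.22 ± 0.13. In these 4 lists 0 members passed over all genes, and adjusted over the list alone 2 did, both erythroid.

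Camera called 15 lists in all at 3 months, and 1, heat shock, with an estimated correlation. The other 9 were reactive astrocytes (median 0.27), lysosome (0.07), interferon response (0.13), antigen presentation (0.12), astrocytes (0.13) and choroid plexus (1.56), which were higher, and excitatory neurons (-0.30), immature neurons (-0.08) and lymphoid cells (-0.30), which were lower. They had an adjusted p of at most 0.0105 and one of at least 0.355 with an estimated correlation. With equal totals 5 of the 9 were not called, interferon response (adjusted p = 0.382), antigen presentation (0.52), astrocytes (0.441), excitatory neurons (0.448) and lymphoid cells (0.269). With the ID prefix as a covariate 5 were not called, reactive astrocytes (0.06, adjusted p = 0.334), lysosome (0.04, 0.0534), immature neurons (-0.04, 0.52), lymphoid cells (-0.30, 0.0569) and choroid plexus. All 18 choroid plexus genes were higher, and with the prefix their median was -0.33 against 0.67 by voom without it (adjusted p = 0.349). A few KO libraries stood out for Ttr, a member of the list, which in Hipp was at 8163 CPM in 5_2, 6945 in 99_2, 3120 in 99_1 and 1915 in 99_3, against at most 413 in the other KO and 747 in WT libraries. In Hind it was at 8145 CPM in 99_3, and in Thal it reached 4250 CPM in KO and 2237 in WT libraries. Without mouse 81_1 immature neurons were not called (-0.05, adjusted p = 0.341). Of the lists closest to the clearance of dying cells, 0 were called with all libraries. Apoptotic cell clearance genes had medians of 0.04 at 18 days (adjusted p = 0.666) and 0.06 at 3 months (adjusted p = 0.0621), and disease-associated microglia 0.09 (adjusted p = 0.0978) and 0.06 (adjusted p = 0.0557). At 3 months both were called as higher without mouse 81_1 (adjusted p = 0.0219 and 0.0193) and with the GC slope as a covariate (adjusted p = 0.0344 and 0.0321). With all mice and an estimated correlation they were not called (adjusted p = 0.355 and 0.411). An estimated correlation was not tried without mouse 81_1 or with the slope. Medians were, for apoptosis and p53 targets -0.06 (adjusted p = 0.166) and 0.01 (adjusted p = 0.919), and lysophosphatidylserine metabolism and receptors 0.01 (adjusted p = 0.537) and -0.02 (adjusted p = 0.919). For the last of these camera gave the direction as up, against the sign of the median.

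By region at 3 months, edgeR called Gpr34 in MC and SSC and 0 genes in Hipp, Hind and Thal. Its log2 fold change was -7.72 ± 0.46 (SE, n = 8 and 4, edgeR adjusted p = 1.85e-06) in MC and -6.18 ± 0.57 (SE, n = 8 and 5, edgeR adjusted p = 0.000381) in SSC, lower in 8 of 8 KO libraries of each. In Hipp, Hind and Thal the filter on low counts removed Gpr34, since mouse 81_1 left too few WT libraries above its limit. Without the filter edgeR did not call it either (adjusted p = 0.292, 0.537 and 0.0544), and without that mouse it was the gene called in each. With the ID prefix as a covariate 0 genes were called in SSC, where Gpr34 stayed at -5.33 ± 0.73 (SE, adjusted p = 0.151). DESeq2 called 2 members of the heat shock list in MC and 1 in Thal. By edgeR, members of that list were among the genes with the smallest p, without passing. They were Hspa1a in MC at 0.91 ± 0.18 (SE, adjusted p = 0.672), Hspa5 in Hind at 0.50 ± 0.12 (adjusted p = 1) and Dnajb1 in Thal at 0.33 ± 0.07 (adjusted p = 1). In Hipp they were P4ha1, a collagen prolyl hydroxylase gene, at 0.39 ± 0.07 (SE) and the stress-induced gene Sesn2 at -0.42 ± 0.08, both with an adjusted p of 0.541. The others were 4930547M16Rik in SSC at -1.12 ± 0.22 (SE, adjusted p = 0.889), Lef1 in Hind at -1.79 ± 0.47 (adjusted p = 1) and the transferrin receptor gene Tfrc in Thal at -0.24 ± 0.05 (adjusted p = 1). At an unadjusted p under 0.05 edgeR had 1364 genes in Hipp, 962 in MC, 685 in SSC, 214 in Hind and 291 in Thal. DESeq2 called 11, 5, 1, 2 and 2.

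The chromosomal neighbours of Gpr34 did not pass in any of the 12 comparisons of KO with WT. Of the 13 tested, log2 fold changes ranged from -0.22 to 0.22 in the 3-month sums and from -0.28 to 0.29 in the 18-day sums, where Maob, at 0.29 ± 0.10 (SE), had the smallest p (edgeR adjusted p = 0.963). Adjusted over the list alone, 1 passed in SSC at 18 days, 2 in Hind and 1 in Thal.

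Whether the KO effect differed between ages was tested as an interaction in 25 mice. edgeR called 0 genes, with 536 at an unadjusted p under 0.05, and DESeq2 called 0. Stk10, a lymphocyte-enriched kinase gene, had the smallest p, with a difference between the log2 fold changes of 0.37 ± 0.09 (SE, adjusted p = 0.98), followed by Fxyd3 at 1.44 ± 0.35 (adjusted p = 0.98). Between regions edgeR called 0 genes at 18 days, with 826 at an unadjusted p under 0.05, and 0 at 3 months, with 530. Without KO mouse 88_7 it called 2 at 18 days. DESeq2 was not run for these, and edgeR without the replicate block of the mouse also called 0 at both ages. The genes with the smallest p were Stk17b and Grxcr2 at 18 days (edgeR adjusted p = 0.4) and Tdrd1 and Gpr25 at 3 months (edgeR adjusted p = 0.998).

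Many genes differed between the ages in WT mice, whose ID prefixes also differ between the ages. In sums over 4 regions 7649 genes passed, 3811 higher and 3838 lower at 3 months than at 18 days (n = 5 and 5). Among the largest rises were Serpinb1a, a protease inhibitor gene, from 0.927 CPM ± 0.452 (SD, n = 5) to 15.98 ± 4.02 (SD, n = 5), a log2 fold change of 4.12 ± 0.31 (SE, edgeR adjusted p = 3.66e-05). Others were the long non-coding RNA Neat1 at 2.62 ± 0.18 (SE), Adamtsl4 at 2.90 ± 0.20, Chdh, an enzyme gene of choline oxidation, at 3.06 ± 0.31. The ion channel gene Pkd2l1 at 3.72 ± 0.36, Etnppl, an astrocyte enzyme gene, at 2.88 ± 0.38 and BC035947 at 2.68 ± 0.48 rose too. Among the largest falls were the cytokine gene Il23a by 4.22 on the log2 scale (SE 0.365), the calcium-sensing receptor gene Casr at -3.80 ± 0.47 and the apelin receptor gene Aplnr at -3.35 ± 0.48. They also held elastin (Eln) at -2.79 ± 0.34, the lipoxygenase gene Alox5 at -2.78 ± 0.22, the replication factor gene Pclaf at -2.80 ± 0.33. Prnd, Dmrta1, Igfbpl1, Mkrn3 and Lefty2 lay between -4.05 and -2.88. These 18 genes moved alike in 5 of 5 mice. Others rested on a few mice. Hmga1b at 4.82 ± 1.53 (SE) was above the 18-day median in 3 of 5 mice, Rps2-ps6 at 3.20 ± 1.09 and Gpr151 at 2.70 ± 0.96 in 2, Abhd12b at 2.71 ± 0.91 in 4, and Lrrc17 at 2.93 ± 0.93 in 5 with 1735 CPM ± 2130 (SD, n = 5). Xist, at -9.60 ± 2.88 (SE), rested on mouse 88_8.

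Proliferation genes fell in 19 of 21 members over all genes and 20 adjusted over the list alone (median -1.65, camera adjusted p = 9.17e-12, and adjusted p = 0.253 with an estimated correlation). Aurkb lay at -2.47 ± 0.15 (SE), Ccnb1 at -1.96 ± 0.15, Rrm2 at -1.66 ± 0.14 and Kif11 at -1.59 ± 0.14. Oligodendrocyte precursor genes fell in 15 of 16 by both adjustments (median -0.94, adjusted p = 4.53e-10, and adjusted p = 0.253 with an estimated correlation). Gpr17 lay at -2.19 ± 0.19 (SE), Vcan at -1.395 ± 0.12, Pdgfra at -1.15 ± 0.09 and Fyn at -0.94 ± 0.07. Immature neuron genes fell in 18 of 20 by both (median -1.02, adjusted p = 2.47e-08, and adjusted p = 0.253 with an estimated correlation). Sox4 lay at -1.39 ± 0.12 (SE), Tubb2b at -1.53 ± 0.15, Dpysl3 at -1.85 ± 0.19 and Igfbpl1 at -3.14 ± 0.30. Interferon response genes rose in 23 of 28 over all genes and 25 adjusted over the list alone, with 1 lower (median 0.84, adjusted p = 1.62e-09, and adjusted p = 0.253 with an estimated correlation). Xaf1 lay at 1.65 ± 0.17 (SE), Ifit3 at 1.39 ± 0.14, Gbp2 at 1.16 ± 0.12 and Ifit1 at 1.78 ± 0.19. Antigen presentation rose in 14 of 16 by both (median 0.89, adjusted p = 2.96e-08, and adjusted p = 0.253 with an estimated correlation). H2-Q4 lay at 0.97 ± 0.08 (SE), H2-K1 at 0.95 ± 0.08, Tap2 at 0.98 ± 0.09 and Psmb8 at 0.78 ± 0.09.

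Immediate early genes of neuronal activity rose with age in 16 of 18 members over all genes and 17 adjusted over the list alone (median 0.97, camera adjusted p = 1.1e-06, and adjusted p = 0.439 with an estimated correlation). Fos lay at 1.72 ± 0.21 (SE), Egr1 at 1.61 ± 0.26, Junb at 1.57 ± 0.24 and Dusp1 at 1.00 ± 0.15. Of the 10 lists called with age, cholesterol synthesis (median -0.62) and perineuronal nets and extracellular matrix (-0.63) were also lower, and heat shock (0.38) and complement (0.40) higher. With an estimated correlation 0 of the 10 were called, with an adjusted p = 0.439 for cholesterol synthesis, 0.269 for heat shock and 0.253 for complement and perineuronal nets.

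By region, edgeR called 6067 genes with age in Hipp, 7933 in MC, 2924 in Hind and 6136 in Thal. It called 0 in SSC, with 2837 at an unadjusted p under 0.05 and 93 called by DESeq2. Without WT mouse 81_1 edgeR called 2311 genes in SSC, and without the SSC libraries of 81_1 and 88_1 it called 5374. That of 88_1 went against its label in Gpr34 (0.022 CPM), but that of 81_1 (8.07 CPM) lay within the WT range. The age score of each lies among libraries of the other age, so the count of 5374 is not independent of age. In Hind 1920 genes were called without WT mouse 88_8. The difference between regions in the effect of age was not tested. In every region and in the sums, WT mice of 18 days carry ID prefix 88 and those of 3 months 5, 7 or 81. Age therefore cannot be told apart from the ID prefix in any region. In Hipp the 3-month and the 18-day libraries are also numbered in separate series in their names, so age there cannot be told apart from a series either.

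**Figure D3:**
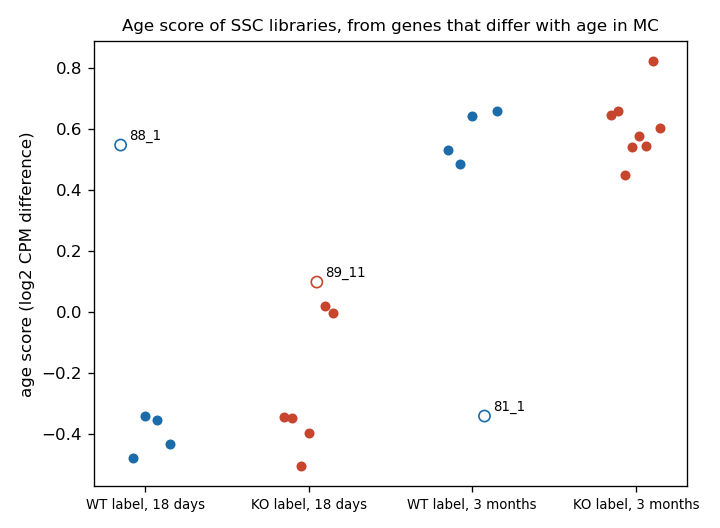
Age score of each SSC library, the mean log2 CPM difference between genes higher and genes lower at 3 months in MC, by age and genotype label. Open circles are the SSC libraries in doubt, those of mice 88_1 (0.547), 81_1 (-0.341) and 89_11 (0.098). Those of 88_1 and 81_1 lie among the libraries of the other age, where medians are -0.35 at 18 days and 0.589 at 3 months. That of 89_11 does not lie among the 3-month libraries, whose lowest score outside those in doubt is 0.448.

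Prnd, a relative of the prion protein gene, was among the 3 largest falls in 4 regions, from 2.92 CPM ± 0.50 (SD, n = 5) in Hipp and 2.52 ± 0.60 (SD, n = 4 at 3 months and 5 at 18 days) in MC to 0 counts in each 3-month library. It went from 3.58 to 0.0481 CPM in Hind (-6.14 ± 0.72 SE) and from 3.95 to 0.0376 CPM in Thal (-6.29 ± 0.78 SE). Aplnr fell in MC by 4.61 (SE 0.187) and in Hind by 4.31 (SE 0.32), Lefty2 in Hipp at -4.66 ± 0.49, and Amdhd1 in Hipp at -4.51 ± 0.47. Further falls were Trpa1 in MC at -4.61 ± 0.59, Il23a in Hind at -4.54 ± 0.65 and Klk1 in Thal at -6.08 ± 1.17. Dhrs7c in Thal went from 2.29 CPM to 0 counts. Rises were led in MC by Hsf4, a heat shock factor gene, at 4.16 ± 0.17 (SE), Cyp2j12 at 4.26 ± 0.75 and Hmga1b at 5.35 ± 1.21. In Thal they were led by Serpinb1a at 4.70 ± 0.32, Igfn1 at 4.35 ± 0.73 and Hmga1b at 4.83 ± 1.58. In Hipp Prg4 at 6.29 ± 1.04 (SE), the hypothalamic peptide gene Pmch at 8.05 ± 2.27 and Sspo at 5.14 ± 1.404 rose, and in Hind Pmch at 5.62 ± 1.63, Lrrc17 at 5.59 ± 1.38 and the oxytocin gene Oxt at 4.48 ± 1.23. Pmch and Oxt had an SD above their mean at 3 months, 40.5 CPM ± 89.1 in Hipp and 2.70 ± 4.99 in Hind for example. In SSC the 2 smallest p belonged to Epha3 at -0.97 ± 0.19 (SE) and Ier5 at 1.15 ± 0.23, both with an adjusted p of 0.259.

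Region markers did not always match the region label. By 7 marker scores 26 of 124 libraries lay nearer the median of another label, among them 9 of 25 labelled Hipp, 6 of 25 labelled Hind, 6 of 25 labelled Thal and 5 of 49 labelled MC or SSC. They made up 5 of 7 KO and 1 of 5 WT libraries of Hipp at 18 days. Without such libraries the KO effect called 3 genes in Hind at 18 days, Gpr34, Wdhd1 and Grxcr2, and Gpr34 alone in Hipp and in Thal at 3 months. The libraries left out include Hind of mouse 89_11 and Hipp and Thal of mouse 81_1, whose Gpr34 goes against the label, so the calls of Gpr34 cannot be put down to the region markers.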

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

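The 8 tests of explanations for the 3 patterns weighed here, and the test of gene lists between ages, were chosen only after the results were seen. Single samples apart from their group were looked for in 244 groups of 4 to 10 samples with Dixon's test at the 95% level, which chance passes in about 5% of groups, or 12.2 of these, and 28 passed.

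Gpr34 stood apart in KO mouse 89_11 at 18 days, at 6.43 CPM in Hind, 6.756 in Hipp, 1.299 in MC, 3.581 in SSC, 7.742 in Thal and 4.903 in the sum, where the nearest other KO value was 0.1278. It stood apart also in WT mouse 88_6 in MC (8.332 CPM, the next being 2.838) and in WT mouse 81_1 in Thal at 3 months (0.05 CPM, the next being 7.067). Library totals stood apart at 105.7 M counts in KO mouse 88_7 in Hind at 18 days, and at 3 months at 44.93 M in KO mouse 5_2 in Hind, 26.37 M in KO mouse 7_3 in Hipp, 40.41 M in WT mouse 7_1 in Hipp and 578.2 M in KO mouse 99_3 in MC. Among named genes in the 18-day sums, the sample apart was WT mouse 88_11 for Gm2861 (0.3278 CPM), WT mouse 88_9 for Slc2a5 (3.527 CPM), and KO mouse 89_6 for the interferon genes Ifit3 (10.22 CPM, the next being 5.944) and Usp18 (2.078 CPM, the next being 0.9459). In the comparison of ages it was mouse 88_1 for Serpinb1a (1.707 CPM) and Prnd (2.2 CPM), mouse 88_8 for Xist (596.5 CPM) and mouse 7_1 for Abhd12b (8.03 CPM) and Xist (0.5482 CPM). Mouse 81_1 stood apart at 3 months for Prnd (0.7743 CPM), Casr (2.129 CPM), Aplnr (2.852 CPM), Mkrn3 (5.204 CPM), Eln (22.96 CPM) and Fyn (150.7 CPM), each above the other 4 mice of its group, and these genes are lower at 3 months than at 18 days.

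The KO effect differed between ages for 8 gene lists by camera with the preset correlation, and for 0 with an estimated correlation, where each of the 8 had an adjusted p = 0.803. Mitochondrially encoded genes (median difference 0.23, adjusted p = 4.11e-07), oligodendrocyte precursors (0.26, 0.000757), proliferation (0.33, 0.00448), choroid plexus (0.82, 0.0113) and reactive astrocytes (0.11, 0.0441) had a higher KO effect at 3 months. Synapse genes (-0.20, 4.11e-07), homeostatic microglia (-0.10, 0.00231) and excitatory neurons (-0.43, 0.00332) had a lower one. Without mice 89_11, 88_1 and 81_1 the excitatory neuron list was not called (adjusted p = 0.0622), while immature neurons (0.000935), interferon response (0.0207) and erythroid cells (0.0217) were. The ID prefix was not part of this test. With it as a covariate at each age the medians at 18 days and 3 months were 0.18 and -0.21 for proliferation, 0.13 and -0.04 for immature neurons, -0.09 and -0.33 for choroid plexus, 0.07 and 0.06 for reactive astrocytes and 0.07 and 0.05 for oligodendrocyte precursors, none of them higher at 3 months. The rest of the 8 lists kept their direction. Their medians were -0.06 and 0.09 for mitochondrially encoded genes and -0.065 and -0.142 for synapse genes. They were -0.114 and -0.252 for homeostatic microglia and -0.177 and -0.411 for excitatory neurons. The library without a group in the labels held 25.92 M counts.

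SSC libraries of WT mice gave 0 genes with age by edgeR, against 7933 in MC. The libraries labelled SSC of mouse 88_1 and SSC of mouse 81_1 may have been exchanged. On a score from 3926 genes higher and 4007 lower with age in MC, 2 of 2 lay nearer the SSC median of the other age, at 0.547 and -0.341 against medians of -0.35 at 18 days and 0.589 at 3 months in 22 other SSC libraries. Tissue of Hipp, Hind or Thal is argued against, since 0 of 2 lay nearer their markers, which do not part MC from SSC, and MC tissue of the labelled age, since 2 of 2 lay outside the scores of MC libraries labelled KO, -0.637 to -0.235 at 18 days and 0.222 to 0.831 at 3 months. Their Gpr34 levels of 0.022 and 8.07 CPM also match the other libraries of the mouse on the other label better than their own, and no biological explanation was tested.

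Mouse 89_11, labelled KO, held more Gpr34 than the other KO mice of its age. A wrong genotype label may account for it, as 5 of 5 libraries had Gpr34 at or above the lowest WT library of any region not in doubt (1.194 CPM, in MC), though its SSC library (3.581 CPM) lay below the 4 WT libraries of SSC not in doubt (6.494 CPM or more). Its Xist level fits a female, so a female with 1 targeted copy is the other candidate explanation. The ratio of its Gpr34 to the WT median of the region had a median of 0.954 and ran from 0.405 in SSC to 1.14 in Thal. The ratio was 0.954 in Hind, 1.017 in Hipp and 1.141 in Thal, which argues against a lowered level in those regions. It was 0.672 in MC and 0.405 in SSC. P2ry12 of this mouse also lay below every WT library of that age in MC and SSC, and in Hipp too. This was not particular to mouse 89_11. KO mice 89_12 and 89_6, of the same ID prefix, also lay below every WT library, at 13.891 and 17.047 CPM in MC and 18.832 and 16.916 in SSC. The low ratios in MC and SSC therefore do not single out 1 targeted copy. The second explanation is not excluded by these values, and no biological explanation was tested.

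Homeostatic microglia genes were lower in KO mice at 3 months, with a median of -0.20. With the ID prefix as a covariate the median was -0.252 (adjusted p = 3.11e-15) and without mouse 81_1 it was -0.23 (adjusted p = 4.39e-22), which argues against either as the whole cause, where prefix 99 is KO and 81 WT throughout, so that the value with the prefix rests on 5 KO and 3 WT mice. A lower share of microglia would lower all members alike, but 9 of 24 differed from the weighted mean of -0.159 by more than 2 SE, with P2ry12 at -0.51 and Ctss at 0.09. An effect of genotype on part of the microglial programme stays open as a hypothesis found and tested on the same data, and the call was lost with an estimated correlation (adjusted p = 0.344). An absolute median as large came up in 2 of the 100 splits, the real one included, and the largest of the others was 0.238.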

How the results depend on the processing

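Results without the libraries in doubt, without libraries nearer another region's markers, with equal totals, with the GC slope, and gene lists with the ID prefix come from tests chosen after the data were seen, and the other alternatives were planned. Of the genes named by the rule, 1417 of 1523 values under an alternative kept direction and side of the threshold, 73 lost their call, 33 gained one and 0 reversed. Of the list members 1361 of 1378 kept both, 9 gained a call and 8 reversed. Of 131 values of Gpr34 at 18 days 115 kept both and 16 gained a call. Of 3483 values of its neighbours 335 turned sign and 0 passed the threshold. Except where stated the cause was not tested.

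DESeq2 called more genes than edgeR, in Hipp 6, MC 5, SSC 3, Hind 48 and Thal 101 at 18 days, in Hipp 11, MC 5, Hind 2 and Thal 2 at 3 months, in sums 4 and 19, and 93 with age in SSC. The joint fit of all libraries of an age called 1 in Hipp (Car13), 1 in MC (Xlr4b), 30 in Hind and 0 in Thal at 18 days, and 1 in Hipp, 8 in SSC, 1 in Hind and 1 in Thal at 3 months. With 1 surrogate variable 1 gene was called in SSC (DXBay18) and 0 in Thal at 18 days, and 2 in the 3-month sums (Gpr34 and P2ry12). With the ID prefix 0 were called in SSC at 3 months, where Gpr34 was at -5.334 ± 0.731 (SE) against -6.18 ± 0.569 without it, a smaller change with a larger SE. Voom with the mouse as a replicate block, on the separate libraries of all 5 regions, called 1 gene at 18 days and 41 at 3 months. Without the libraries in doubt 1 gene was called in Hipp, MC, SSC and Hind and 2 in Thal at 18 days, 1 in Hipp, Hind and Thal at 3 months, 1 in the 18-day sums, and 5374 with age in SSC, and the Gpr34 level was -6.353. Each of these KO calls is or includes Gpr34, by which the libraries were picked. Without libraries nearer another region's markers 3 genes were called in Hind at 18 days, and 1 in Hipp and 1 in Thal at 3 months, where this also left out libraries of 89_11 and 81_1, and in Thal at 18 days the 1 gene called was Gpr34 in place of Adgrd1. The lists called were 0 at 18 days, 1 at 3 months and 0 with age under an estimated correlation, and 7 at 18 days without the mice in doubt.

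With each mouse left out in turn, counts ran from 0 to 1 in Hipp (1 without 89_11), MC (88_1 or 89_11), SSC (88_7), Hind (88_1, 88_6 or 89_11) and the sums (89_11) at 18 days, from 0 to 2 in Thal, from 0 to 1 in Hipp, Hind and Thal at 3 months (81_1), and from 1 to 2 in the 3-month sums (7_3). They ran from 0 to 2 between regions at 18 days (88_7), from 0 to 2311 with age in SSC (81_1) and from 1920 to 3317 with age in Hind (88_8 and 88_6). They stayed at 1 in MC and SSC at 3 months and at 0 for the age interaction and between regions at 3 months. Counts with age ran from 6415 to 7789 in sums, 4934 to 6236 in Hipp, 6736 to 7976 in MC and 5058 to 6550 in Thal, and of lists from 8 to 16 at 18 days, 14 to 20 at 3 months and 10 to 12 with age. Members that turned were, at 18 days, C2 with length offsets (0), Dlx6os1 with voom and the replicate block (-0.002), and with the ID prefix H2-T23 (-0.121), Nrep (0.029), Mcm2 (0.045), Bub1 (0.036), Cenpf (0.088) and Top2a (0.11), none of them past the threshold.

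Depth limits Gpr34 in KO libraries, of which, among those not in doubt, 1 at 18 days and 8 at 3 months had 0 counts. In simulated counts of a region edgeR recovered 61.2% (Thal) to 80.6% (SSC) of 2-fold changes at 18 days, and 23.9% (Hipp and Hind) to 59.7% (MC) of 1.5-fold changes at that age. At 3 months it recovered 62.7% (Hind) to 82.1% (MC) of 2-fold and 14.9% (Hind) to 71.6% (SSC) of 1.5-fold changes.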

Other observations

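Tests by DESeq2 and the joint fit were planned, while the results given in this paragraph were picked after their values were seen. In Thal at 18 days DESeq2 called 101 genes, 85 higher and 16 lower in KO libraries. In 3 of the 7 KO libraries and 0 of the 5 WT libraries of that group the marker scores lay nearer another region. In Hind at 18 days the joint fit called 30 genes, all lower, where cerebellum marker scores ran from 2.61 to 4.96 in KO and from 2.73 to 7.47 in WT libraries.

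Other splits of the same mice, planned for each result, gave these counts. A count of 0 was matched by 100 of the 100 splits, and the highest other count was 0 in Hipp, 11 in MC, 0 in SSC and 3 in Hind at 18 days, 648 in Hipp, 1 in Hind and 3 in Thal at 3 months, 16 for the 18-day sums, 2 for the age interaction, 806 between regions at 18 days, 2455 between regions at 3 months and 12 for age in SSC. For the call in Thal at 18 days 2 of the 100 splits gave as many, the highest other being 1. For the 3-month sums 3 of the 100 did, the highest other being 272. Since 12 comparisons of KO with WT were split this way, these shares do not exclude chance for a count of 1 gene. In the 3-month sums that gene is Gpr34, the targeted gene itself. Chance is not excluded either for a count of 1 gene in MC at 3 months (7 of the 100 splits, highest other 101) or in SSC (5 of the 100, highest other 2). These counts do not test the gene itself, Gpr34, which was at most 0.073 CPM in KO and at least 3.202 CPM in WT libraries of MC, and at most 0.14 and at least 0.866 CPM in SSC. Splits with many times the real count of 1, up to 101 in MC and 272 in sums at 3 months, point to a structure among the mice other than genotype, whose nature was not tested. For age, 1 of the 100 splits, the real one, gave as many genes in sums (7649, highest other 9), Hipp (6067, highest other 159), MC (7933, highest other 4676), Hind (2924, highest other 89) and Thal (6136, highest other 16). The real count thus lay above that of every other split drawn. A share of 1 of the 100 is the smallest that these splits can give, so they cannot exclude chance at a stricter level. The splits do not part age from the ID prefix. Counts of gene lists did not exclude chance, with 51 of the 100 splits at 18 days (real 11, highest other 20), 6 of the 100 at 3 months (real 15, highest other 17) and 68 of the 100 with age (real 10, highest other 19).

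The library that the labels put in no group held 1 count of Gpr34, or 0.039 CPM, where 3 counts would be 0.116 CPM. Its library name holds MC and a number near that of WT mouse 81_1, which has no library labelled MC, but it was not assigned on that ground, and the value is not used to judge the label of that mouse. Xist was at 0 CPM and Ddx3y at 28.955 CPM, P2ry12 at 12.487 CPM, and its marker scores lay nearest those of libraries labelled MC or SSC.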
